A study of Mus musculus with 6 samples.

How the data were processed

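Poly(A) RNA of aortic tissue from mice aged 32 weeks was sequenced in 3 wild-type samples and 3 samples carrying the Fbn1C1041G/+ genotype, per the labels. The authors deposited 1 table of FPKM values per gene and sample, per the file headers, rounded to 2 decimals. Mouse genome build mm9 is listed in the submitters' processing notes, and the aligner, the quantifier and the annotation are not given in the sources used here. No raw counts were used, so no count model was fitted. The table had 21117 genes under NCBI gene numbers, of which 21059 were matched to a symbol through a RefSeq gene table of the GRCm38.p6 assembly and 58 were not, and since that assembly is not the one the authors used, no coordinates are given. The columns were mapped to the samples by name, and 0 columns of sample values were left unmapped.

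FPKM values keep no read numbers. In genes with 1 transcript, low values fell on steps set by the length of the transcript, and these steps were used to estimate the depth of each library. With the estimated depth, 75.7% to 79.7% of such values lay within 0.2 of a whole fragment, where chance gives 40% for a step fixed beforehand. The step was chosen as the best fit to these same values, so chance would give more than 40% here, and how much more was not computed. The estimated depths were 16230000, 16720000 and 13960000 fragments in WT and 16980000, 14470000 and 15960000 fragments in Fbn1C1041G/+ replicates 1 to 3. No intervals were computed from them. The labels do not say that the samples of a group came from separate animals, so p-values measure the spread between these samples. No pair of libraries shared more than 1.76% of its non-zero values, and no library was counted as a repeat of another.

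Values were taken to log2(FPKM + 1), a scale on which the change of low genes is understated, and 13438 genes with a mean of at least 1 FPKM over the 6 samples were tested, which left out 7679 genes. The groups were compared with limma 3.58.1 in R 4.3.3, by lmFit and eBayes with a trend in the mean, 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are Fbn1C1041G/+ minus WT. Gene lists, 31 in number and fixed before the data were examined, were tested with camera at a preset correlation between genes of 0.01, for lists with at least 5 tested members and with adjustment over the 30 lists tested; the list of sex-specific genes was not tested. Camera with an estimated correlation and the directional fry test were run beside it. The named genes were also chosen by a rule fixed before the data were examined. It took Fbn1 and Spp1, the 12 called genes with the largest change in each direction whose groups did not overlap, without predicted or clone symbols, and of each list described up to 4 members with the smallest unadjusted p and its first member. Some genes that the rule selects are not reported here. An exact 2-sided permutation test of 3 against 3 samples cannot give a p below 0.1. Sex-linked transcripts were alike in the 6 samples, with Xist at 0.01 to 0.04 FPKM and Ddx3y at 10.8 to 16.7 FPKM.

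The alternatives fixed before the data were examined were pseudocounts of 0.1 and 0.01, no filter on low values, a filter at a mean of 5 FPKM, quantile normalization, median-ratio scaling, limma without a trend or with robust moderation, sample weights, the replicate number as a block, each library left out, and other thresholds. Values corrected for GC content were added after the data were examined. For these a loess curve of span 0.3 of each library's deviation from the gene means on transcript GC content was removed, for the 99.0% of tested genes with a GC value. 6 short gene lists, of nerve, glial, myelin, atrial, and ventricular and slow muscle genes, were also written after the data were examined and are used only in the closing observations.

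The tests were run first on simulated data for this comparison, with 13438 genes, depth as in the real libraries and 50 genes changed at each fold. The spread was the moderated residual spread of log2(FPKM + 1), with counting noise added on top of it. That residual spread already holds counting noise, so the simulated spread was not exactly that of the real libraries. In the simulation 13238 genes were left unchanged, while the real comparison called 752. Recovery in the real data can therefore differ. The limma test recovered 4% of genes changed by 1.5-fold, 44% of those changed by 2-fold, 94% at 4-fold and 98% at 8-fold, and 5.51% of its calls were false. Genes were independent of each other in the simulation, which therefore says nothing of how camera behaves on genes that vary together. Figures were drawn with matplotlib 3.10.9.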

Results

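The transcriptome of mouse aortic tissue was measured by poly(A) RNA sequencing at 32 weeks of age in 3 wild-type (WT) samples and 3 samples heterozygous for Fbn1C1041G, a missense allele of the fibrillin-1 gene that is used as a mouse model of Marfan syndrome. All samples were labelled untreated. The values were FPKM, fragments per kilobase of transcript scaled to the number of mapped fragments, for 21117 genes. The steps between low values put the depth at 13960000 to 16720000 fragments in WT and 14470000 to 16980000 in Fbn1C1041G/+ samples, so that 1 FPKM in a transcript of 2 kb rested on about 27.9 to 34.0 fragments. Spearman correlations between libraries, taken across genes, were 0.927 to 0.978 within WT, 0.954 to 0.970 within Fbn1C1041G/+ and 0.907 to 0.943 between the groups. WT replicate 3 lay apart from the other libraries on the second principal component, with a score of -45.80 against -5.10 to 23.13 in the rest. In that library GC-rich genes had lower values than in the other WT libraries, and the correlation across genes of its deviation with GC content was -0.28, against 0.19 and 0.28 in WT replicates 1 and 2. The mutant libraries also differed from each other in this, with correlations of 0.27, -0.17 and -0.19 in Fbn1C1041G/+ replicates 1 to 3.

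The design asked which genes differ between mutant and wild-type aortas. Fbn1 (NCBI gene 14118), the mutated gene, stood at 18.8 ± 2.93 FPKM (SD, n = 3) in WT and 24.2 ± 3.81 FPKM (SD, n = 3) in Fbn1C1041G/+ samples. The log2 fold change was 0.35 ± 0.17 (SE; limma adjusted p = 0.432), and a missense allele need not alter the transcript level, so this value did not check the labels. Spp1 (NCBI gene 20750), which encodes osteopontin, a secreted matrix glycoprotein and the gene in the title of the series, stood at 5.86 ± 0.403 FPKM (SD, n = 3) in WT and 25.1 ± 16.7 FPKM (SD, n = 3) in Fbn1C1041G/+ samples. Its 3 mutant values of 43.9, 11.8 and 19.5 FPKM all lay above the WT values of 6.01, 5.40 and 6.16 FPKM. The log2 fold change of 1.73 ± 0.41 (SE) did not pass the threshold (limma adjusted p = 0.0621). Without Fbn1C1041G/+ replicate 1 the log2 fold change was 1.24 with an adjusted p of 0.0464, and without Fbn1C1041G/+ replicate 2 it was 2.15 with an adjusted p of 0.0218. With sample weights it was 1.52 with an adjusted p of 0.0216. With the replicate number as a block it was 1.73 with an adjusted p of 0.0330, though such a pairing was not shown for every replicate. In the other direction, the adjusted p was 0.164, 0.191 and 0.0971 without WT replicates 1, 2 and 3, 0.171 without Fbn1C1041G/+ replicate 3 and 0.104 with no filter on low values.

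The genes with the largest fall in Fbn1C1041G/+ aortas included Th and Dbh, which encode enzymes of catecholamine synthesis, and those with the largest rise included Myh6 and Tnni3, which encode contractile proteins of heart muscle. Of 13438 genes tested, 652 were lower and 100 were higher at an adjusted p under 0.05 (limma on log2(FPKM + 1)), of which 495 and 78 differed by at least 2-fold on that scale. The 3 values of one group lay wholly above those of the other for every one of these 752 genes, and for 19.99% of all tested genes, where chance gives 10%. Together the lower genes held 4.50% of the summed FPKM in WT and 1.45% in Fbn1C1041G/+ samples. Leaving out single libraries moved the lower count to 389 without WT replicate 1, 413 without WT replicate 2 and 397 without Fbn1C1041G/+ replicate 3. The higher count was 37 without WT replicate 1, 39 without WT replicate 2, 47 without Fbn1C1041G/+ replicate 1, 192 without Fbn1C1041G/+ replicate 2 and 47 without Fbn1C1041G/+ replicate 3.

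**Figure D1:**
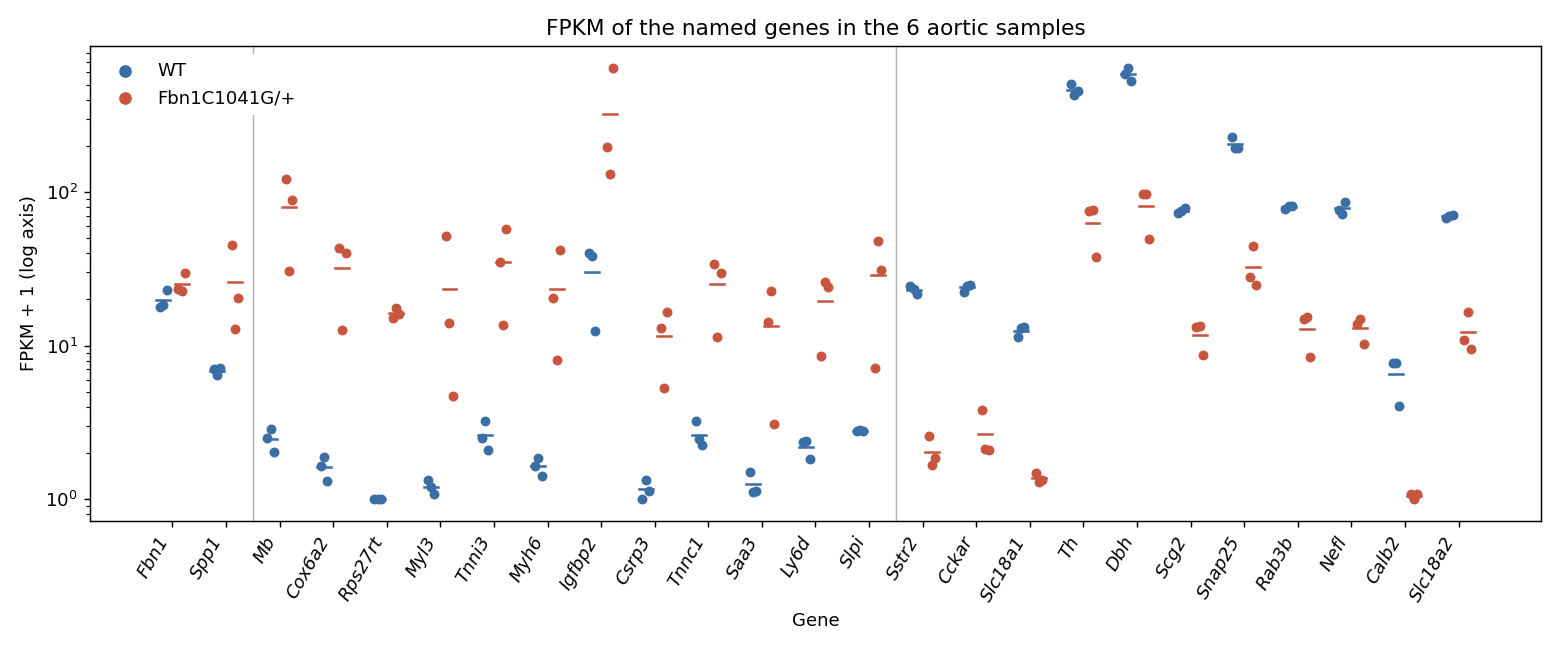
FPKM + 1 on a log axis for Fbn1, Spp1, the 12 genes with the largest rise and 11 of the 12 with the largest fall, one point per library (WT blue, Fbn1C1041G/+ red) and a bar at the mean of each group (n = 3). Th sat between 429 and 500 FPKM in WT and between 36.7 and 75.2 FPKM in mutant libraries, while Mb sat between 1.02 and 1.88 FPKM in WT and between 29.5 and 121 FPKM in mutant libraries.

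Among the 12 genes with the largest fall were genes of catecholamine synthesis, secretion and the neuronal cytoskeleton. Th, tyrosine hydroxylase, the rate-limiting enzyme of catecholamine synthesis, stood at 460.3 ± 36.4 FPKM (SD, n = 3) in WT and 62.0 ± 21.9 FPKM (SD, n = 3) in mutant samples, a log2 fold change of -2.94 ± 0.28 (SE; limma adjusted p = 0.00227). Dbh, dopamine beta-hydroxylase, which makes noradrenaline, stood at 585.5 ± 60.1 and 80.0 ± 27.3 FPKM (SD, n = 3 each), with a log2 fold change of -2.92. The vesicular monoamine transporters Slc18a1 and Slc18a2 had log2 fold changes of -3.19 and -2.54. Sstr2, a somatostatin receptor, had the largest fall, from 22.1 to 1.04 FPKM (log2 fold change -3.52), and Cckar, a cholecystokinin receptor, fell from 22.9 to 1.67 FPKM (log2 fold change -3.22). Scg2, a secretory granule protein, Snap25, a synaptic vesicle fusion protein, and Rab3b, a GTPase of regulated secretion, had log2 fold changes of -2.71, -2.70 and -2.69. Nefl, the neurofilament light chain, and Calb2, the calcium-binding protein calretinin, had log2 fold changes of -2.60 and -2.57. The 12 genes had adjusted p values of 0.000483 to 0.00393 in the limma test, and all 12 stayed past the threshold under every alternative in which they were tested. On the list of Schwann cell and neuronal markers, 5 of 11 tested members fell, none rose and 6 were not called, and 6 fell when adjusted over the list alone. Besides Th and Dbh, the glial genes S100b (log2 fold change -0.83) and Gfra3 (-0.83) were among them. The call of S100b ended without any library but WT replicate 3 and Fbn1C1041G/+ replicate 1 (adjusted p up to 0.0955). The myelin gene Mbp had a log2 fold change of -0.47 and was not called; Gfra3 and Mbp were picked from the list after their values were seen. The list median was -0.83, with an adjusted p of 1.4e-05 in the camera test and an adjusted p of 0.290 with an estimated correlation.

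Among the 12 named genes with the largest rise, 7 encode proteins of heart or other striated muscle. Mb, myoglobin, stood at 1.47 ± 0.431 FPKM (SD, n = 3) in WT and 79.3 ± 46.4 FPKM (SD, n = 3) in Fbn1C1041G/+ samples, a log2 fold change of 4.82 ± 0.48 (SE; limma adjusted p = 0.00241). Cox6a2, a muscle isoform of a cytochrome c oxidase subunit, rose by 4.13 on the log2 scale. The contractile genes Myl3, Tnni3, Myh6 and Tnnc1 rose by 3.64, 3.55, 3.54 and 3.12, and Csrp3, a Z-disc protein, rose by 3.18. Myl3 was 50.6, 12.98 and 3.71 FPKM in the mutant libraries and at most 0.34 FPKM in WT. Its call ended without WT replicate 1, 2 or 3 or Fbn1C1041G/+ replicate 2 (adjusted p 0.0727 to 0.121), and that of Myh6 ended without Fbn1C1041G/+ replicate 1 (adjusted p 0.0553). On the cardiomyocyte list 5 of 12 tested members rose, none fell and 7 were not called, and 9 rose when adjusted over the list alone. Tnnt2, cardiac troponin T, rose from 15.6 ± 7.22 to 104.8 ± 43.4 FPKM (SD, n = 3 each), and Mybpc3, cardiac myosin-binding protein C, rose from 0.0533 to 4.07 FPKM. The list median was 2.36, with an adjusted p of 1.3e-09 in the camera test and an adjusted p of 0.238 with an estimated correlation. On the skeletal muscle list 2 of 10 tested members rose, Mb and the creatine kinase gene Ckm (log2 fold change 2.20), none fell and 8 were not called, and 5 rose when adjusted over the list alone. Mb and Ckm are also expressed in heart muscle, whose markers were higher in the same samples, so these 2 calls do not single out skeletal muscle. Acta1, skeletal muscle actin, stood at 62.1, 19.95 and 1.83 FPKM in the mutant libraries and at 3.04 to 5.20 FPKM in WT, and was not called. In Fbn1C1041G/+ replicate 3, where Acta1 was 1.83 FPKM, Mb was still 87.3 FPKM. The skeletal list median was 1.82, with an adjusted p of 2.2e-07 in the camera test and an adjusted p of 0.290 with an estimated correlation.

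The other 5 genes with the largest rise came from several families. Igfbp2, an insulin-like growth factor binding protein, stood at 29.2 ± 15.3 FPKM (SD, n = 3) in WT and 323.5 ± 280.6 FPKM (SD, n = 3) in mutant samples, with a log2 fold change of 3.26. The acute-phase gene Saa3, the surface antigen gene Ly6d and the protease inhibitor gene Slpi had log2 fold changes of 3.01, 3.01 and 2.98. Leaving out a single library ended the call of Igfbp2 for any library but Fbn1C1041G/+ replicate 2, of Saa3 for any but Fbn1C1041G/+ replicate 3 and of Slpi for any but Fbn1C1041G/+ replicate 1, with adjusted p up to 0.101, 0.166 and 0.159. With all libraries in the fit, Saa3 and Slpi had limma adjusted p values of 0.0497 and 0.0402. Both calls also ended with robust moderation (0.0621 and 0.0505), a filter at a mean of 5 FPKM (0.0683 and 0.0503) and no filter (0.0905 and 0.0755). The call of Saa3 ended with quantile normalization (0.0561) and median-ratio scaling (0.0501) as well. Rps27rt, a retrogene copy of the ribosomal protein gene Rps27, was listed at 0 in every WT library and at 14.1, 16.7 and 15.1 FPKM in the mutant libraries. Its reads can be shared with Rps27 itself, which stood at 962.1 to 1144 FPKM in WT and 1138 to 1649 FPKM in mutant libraries, so the level of Rps27rt is uncertain. Neither read sharing nor a strain difference between the groups was tested for it.

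Single genes of the macrophage, B cell and chemokine lists rose in Fbn1C1041G/+ aortas. On the macrophage and monocyte list, 4 of 22 tested members rose, none fell and 18 were not called, and 12 rose when adjusted over the list alone. Ly6c2, a monocyte surface antigen, rose from 2.06 ± 0.529 to 20.1 ± 7.13 FPKM (SD, n = 3 each; log2 fold change 2.75), and the chemokine receptor gene Ccr2 from 1.35 to 5.23 FPKM. The lysozyme gene Lyz2 rose from 123.9 to 316.7 FPKM and the Fc receptor gene Fcgr1 from 1.44 to 4.83 FPKM. The calls of Lyz2 and Fcgr1 ended without any library but Fbn1C1041G/+ replicate 2 (adjusted p up to 0.171 and 0.123). Cd68 stood at 13.6 ± 2.52 FPKM in WT and 36.3 ± 28.9 FPKM in mutant samples (SD, n = 3 each) and was not called. The list median was 0.95, with an adjusted p of 3.3e-12 in the camera test and an adjusted p of 0.290 with an estimated correlation. None of the 12 tested T and NK cell genes was called over all genes, while all 12 rose when adjusted over the list alone, Il7r (log2 fold change 1.18) and Cd3g (1.46) among them, and Cd3e had a log2 fold change of 1.14. That list's median of 1.26 had an adjusted p of 4.3e-08 in the camera test and an adjusted p of 0.364 with an estimated correlation. The estimated correlation between its members was 0.90, so the 12 genes were far from 12 separate observations. Relative to the WT mean, the T and NK median was 1.28, 0.34 and 2.12 in Fbn1C1041G/+ replicates 1 to 3. The groups did not overlap for 9 of the 12 genes. On the B cell and plasma cell list, Mzb1, a plasma cell endoplasmic reticulum protein, rose (log2 fold change 2.21), 8 of 9 tested members were not called, and 8 rose when adjusted over the list alone, with Cd79a at a log2 fold change of 2.22. The call of Mzb1 (limma adjusted p 0.0497) ended without any library but Fbn1C1041G/+ replicate 3 (adjusted p up to 0.149). It also ended with quantile normalization (0.0604), median-ratio scaling (0.0597), robust moderation (0.0612) and no filter on low values (0.0902). The median of 1.47 had an adjusted p of 6.1e-07 in the camera test and an adjusted p of 0.290 with an estimated correlation. Relative to the WT mean, the B cell median was 1.41, 0.46 and 2.68 in Fbn1C1041G/+ replicates 1 to 3. The groups did not overlap for 4 of its 9 genes. None of 8 neutrophil genes was called over all genes and 2 rose when adjusted over the list alone, Csf3r (log2 fold change 0.76) and Retnlg (1.91), while S100a8 reached 65.0 FPKM in Fbn1C1041G/+ replicate 2 and at most 3.33 FPKM in the other libraries. The neutrophil median of 1.07 had an adjusted p of 0.00600 in the camera test and an adjusted p of 0.444 with an estimated correlation. Relative to the WT mean it was 0.59, 2.08 and 0.40 in Fbn1C1041G/+ replicates 1 to 3, and without Fbn1C1041G/+ replicate 2 the list median was 0.38 (adjusted p 0.0415). Of 17 cytokine, chemokine and adhesion genes, the chemokine gene Ccl8 rose from 9.59 to 50.5 FPKM, 16 were not called and 1 rose when adjusted over the list alone. The call of Ccl8 ended without any library but WT replicate 3 and Fbn1C1041G/+ replicate 1 (adjusted p up to 0.123). Cxcl12 and Vcam1 had log2 fold changes of 0.68 and 0.82. The list median of 0.51 had an adjusted p of 2.0e-05 in the camera test and an adjusted p of 0.290 with an estimated correlation.

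**Figure D2:**
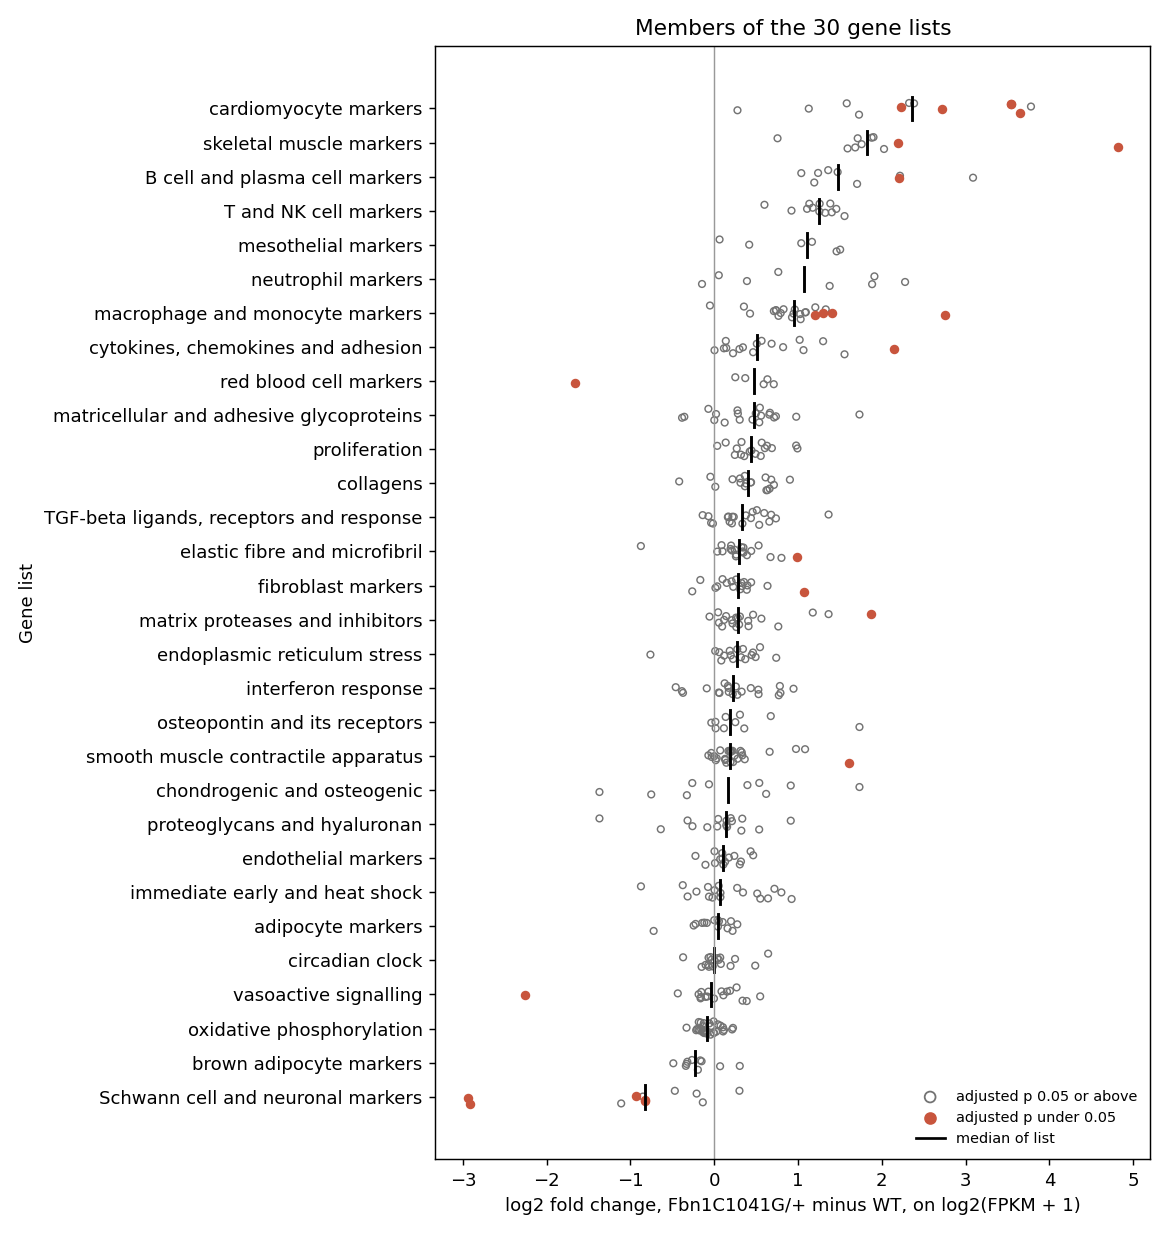
Log2 fold change (Fbn1C1041G/+ minus WT, on log2(FPKM + 1)) of each tested member of the 30 gene lists, with filled points at an adjusted p under 0.05 and a black bar at the list median. The cardiomyocyte list had the highest median, 2.36, and the Schwann cell and neuronal list the lowest, -0.83.

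Genes of the contractile apparatus and of the matrix, the processes named in the title of the series, differed little one by one. Acta2, smooth muscle actin, stood at 5349 ± 498 FPKM (SD, n = 3) in WT and 5381 ± 873 FPKM (SD, n = 3) in Fbn1C1041G/+ samples, with a log2 fold change of 0.00041 ± 0.18 (SE; limma adjusted p = 0.99985). Its sign turned with quantile normalization (-0.032). Of 28 tested contractile genes, Pln, phospholamban, rose from 5.07 ± 0.411 to 17.7 ± 2.97 FPKM (SD, n = 3 each), none fell and 27 were not called, and 1 rose when adjusted over the list alone. Pln and Casq2 (log2 fold change 1.08) are also expressed in heart muscle, whose markers were higher in the same samples. The contractile list median was 0.19, with an adjusted p of 0.00151 in the camera test and an adjusted p of 0.419 with an estimated correlation, and the camera call ended without WT replicate 3 (median 0.0999; adjusted p 0.0589). None of 18 collagen genes was called over all genes or adjusted over the list alone. Col8a1 and Col14a1 had log2 fold changes of 0.66 and 0.64, and Col1a1 stood at 314.7, 230.4 and 46.3 FPKM in WT and at 144.5 to 244.9 FPKM in mutant libraries. The collagen median was 0.41, with an adjusted p of 0.00151 in the camera test, an adjusted p of 0.444 with an estimated correlation, an adjusted p of 0.431 without WT replicate 3 (median 0.082) and an adjusted p of 0.0630 with sample weights (median 0.23). Without that library the log2 fold change of Col1a1 was -0.40 in place of 0.44, and that of Eln, elastin, was -0.27 in place of 0.34. Of 20 elastic fibre and microfibril genes, Ltbp2, a latent TGF-beta binding protein, rose (log2 fold change 0.98; adjusted p 0.0499), 19 were not called, and none passed when adjusted over the list alone. The call of Ltbp2 ended without any 1 of the 6 libraries (adjusted p 0.0814 to 0.133). Mfap4 had a log2 fold change of -0.88 and was not called. The median of 0.29 had an adjusted p of 0.00373 in the camera test and an adjusted p of 0.423 with an estimated correlation, and the camera call ended without WT replicate 3 (median 0.026; adjusted p 0.359), without Fbn1C1041G/+ replicate 3 (adjusted p 0.0562) and with sample weights (median 0.033; adjusted p 0.0630).

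Other matrix lists gave a similar picture of small values in single genes. None of 20 matricellular and adhesive glycoprotein genes was called over all genes or adjusted over the list alone. Fn1, fibronectin, stood at 319.8 ± 58.5 FPKM in WT and 524.3 ± 82.1 FPKM in mutant samples (SD, n = 3 each), with a log2 fold change of 0.71 (limma adjusted p = 0.105), and Ccn3 had one of 0.50. The median of 0.48 had an adjusted p of 0.000310 in the camera test and an adjusted p of 0.290 with an estimated correlation, and was 0.27 without Fbn1C1041G/+ replicate 3. Of 21 matrix protease and inhibitor genes, the cathepsin gene Ctss rose from 16.7 ± 2.87 to 65.6 ± 20.7 FPKM (SD, n = 3 each), none fell and 20 were not called, and 1 rose when adjusted over the list alone. Ctss is abundant in macrophages, whose markers were higher in the same samples. Mmp2 stood at 48.2 and 47.4 FPKM in the WT and mutant groups, and Mmp3 had a log2 fold change of 0.56. The protease median of 0.28 had an adjusted p of 3.5e-05 in the camera test and an adjusted p of 0.290 with an estimated correlation. None of 21 genes of TGF-beta ligands, receptors and response was called over all genes or adjusted over the list alone. Tgfbr2 had a log2 fold change of 0.38. Tgfb1 was 4.85 FPKM in WT replicate 3 and 24.5 to 41.8 FPKM elsewhere, and its log2 fold change of 0.68 was -0.21 without that library. The TGF-beta median of 0.34 had an adjusted p of 0.00278 in the camera test and an adjusted p of 0.290 with an estimated correlation, and the camera call ended without WT replicate 3 (median 0.19; adjusted p 0.0845). Without Fbn1C1041G/+ replicate 3 the median was 0.20. On the list of osteopontin and its receptors none of 10 members was called over all genes, and Spp1 alone rose when adjusted over the list alone. Cd44 was not called, with a log2 fold change of 0.31, and of 0.042 without Fbn1C1041G/+ replicate 3. The median of 0.19 had an adjusted p of 0.0276 in the camera test and an adjusted p of 0.419 with an estimated correlation, and the camera call ended without WT replicate 3 (adjusted p 0.0845), without Fbn1C1041G/+ replicate 3 (median 0.015; adjusted p 0.339) and with a filter at a mean of 5 FPKM (adjusted p 0.0564). The median was 0.35 without Fbn1C1041G/+ replicate 1 and 0.33 with sample weights. Of 18 fibroblast markers, Tcf21, a transcription factor of fibroblast lineages, rose (log2 fold change 1.08), 17 were not called, and 1 rose when adjusted over the list alone. The call of Tcf21 ended without any library but WT replicate 2 (adjusted p up to 0.146). Pdgfra had a log2 fold change of 0.15. The fibroblast median of 0.29 had an adjusted p of 0.00244 in the camera test and an adjusted p of 0.419 with an estimated correlation, and the camera call ended without Fbn1C1041G/+ replicate 1 (median 0.088; adjusted p 0.0840).

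**Figure D3:**
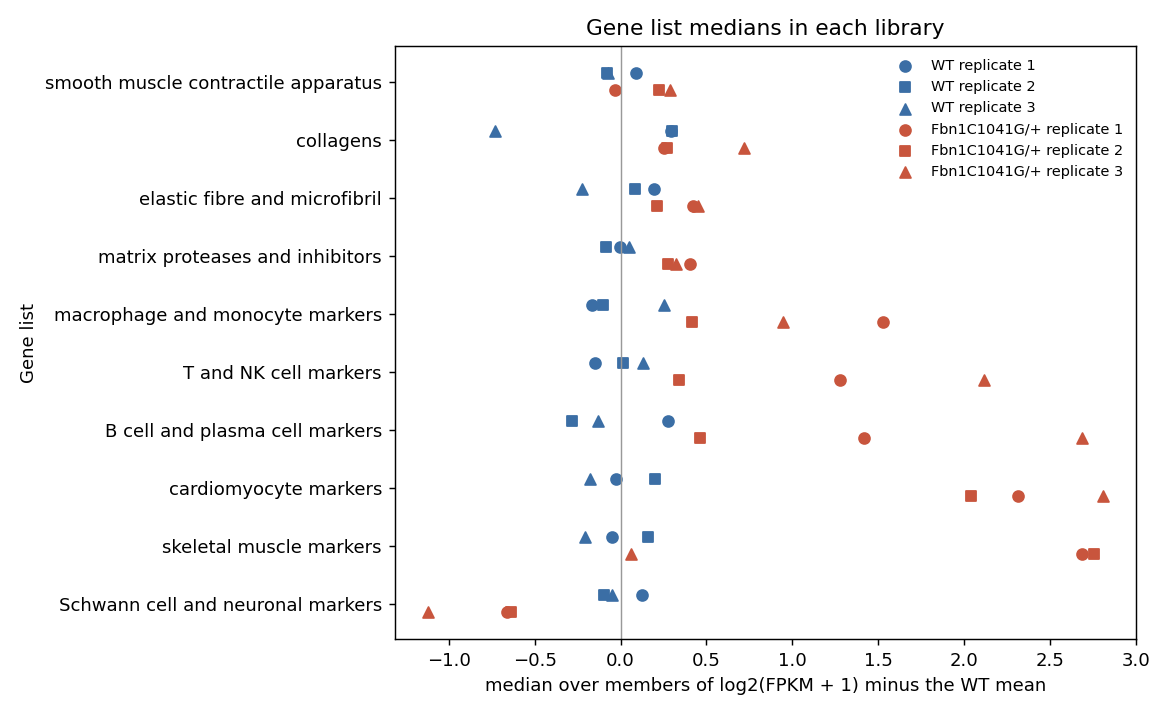
Median over list members of log2(FPKM + 1) minus the WT mean in each library, for 10 of the lists, with WT in blue and Fbn1C1041G/+ in red and the replicate number as the marker. WT replicate 3 stood at -0.73 for collagens, and Fbn1C1041G/+ replicate 3 stood at 0.06 for skeletal muscle where the other mutant libraries stood at 2.69 and 2.76.

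Of the remaining lists, those of proliferation, interferon response, mesothelial markers and endoplasmic reticulum stress passed the camera test, with medians of 0.44, 0.22, 1.10 and 0.27. Their adjusted p values were 1.4e-05, 0.00373, 0.00858 and 0.0321 in the camera test, against adjusted p values of 0.419, 0.444, 0.364 and 0.545 with an estimated correlation. No member of these lists was called over all genes, and adjusted over the list alone 2 of 6 mesothelial genes rose, Upk3b (log2 fold change 1.46) and Upk1b (1.504), and none of the 17 proliferation, 21 interferon or 17 endoplasmic reticulum stress genes. The mesothelial call ended without WT replicate 3 (adjusted p 0.0625). The interferon call ended with a filter at a mean of 5 FPKM (adjusted p 0.142), and its median was 0.34 and 0.12 without WT replicates 1 and 2 and 0.35 with sample weights. The endoplasmic reticulum call ended without WT replicate 1 (adjusted p 0.217), WT replicate 3 (0.136) or Fbn1C1041G/+ replicate 3 (0.499; median 0.11), with median-ratio scaling (0.0539) and with sample weights (0.0630). Its median was 0.44 without WT replicate 2 and 0.42 without Fbn1C1041G/+ replicate 1. The proliferation median was 0.24 without Fbn1C1041G/+ replicate 1 and 0.68 without Fbn1C1041G/+ replicate 2. Ube2c and Ccnb2 of the proliferation list had log2 fold changes of 0.99 and 0.98, and Irf7 and Oas2 of the interferon list had 0.95 and 0.79. In the other direction, Ifit1 of the interferon list had -0.46 and Asns of the endoplasmic reticulum list -0.76 (limma adjusted p 0.274 and 0.126), with every mutant value below every WT value for both genes. The vasoactive signalling list did not pass (median -0.036, mean -0.085, direction of the camera test upward; adjusted p = 0.754), but its member Agtr1a, the angiotensin II type 1a receptor, fell from 53.9 ± 3.96 to 10.8 ± 3.38 FPKM (SD, n = 3 each), a log2 fold change of -2.26 ± 0.23 (SE; limma adjusted p = 0.00262). It was the 1 member of 18 to be called, also when adjusted over the list alone. In Fbn1C1041G/+ replicates 1 to 3 Agtr1a stood at 12.3, 13.2 and 6.94 FPKM, beside 74.1, 75.2 and 36.7 FPKM for Th and 95.9, 95.5 and 48.4 FPKM for Dbh, which were lower in the same samples. The red blood cell list did not pass (median 0.48; adjusted p = 0.488), with 1 of 6 members called, downward. Without Fbn1C1041G/+ replicate 1 it passed (median 0.87; adjusted p 0.00704), and its median was 0.27 without WT replicate 1 and 0.18 without Fbn1C1041G/+ replicate 3. The list medians of endothelial, proteoglycan, chondrogenic and osteogenic, and immediate early and heat shock genes were 0.11, 0.15, 0.17 and 0.074, with adjusted p values of 0.187, 0.413, 0.315 and 0.488 in the camera test. For adipocyte, brown adipocyte, oxidative phosphorylation and circadian clock genes the medians were 0.041, -0.23, -0.090 and -0.0067, with adjusted p values of 0.778, 0.732, 0.713 and 0.738. Of these 8 lists, 5 passed the camera test in single alternatives. Endothelial genes passed with sample weights (median 0.24; adjusted p 0.0378) and without WT replicate 3 (0.14; 0.0275), and adipocyte genes without WT replicate 3 (0.42; 0.00829). Oxidative phosphorylation genes passed without WT replicate 1 (-0.18; 0.0332), and chondrogenic and osteogenic genes (0.23; 0.0491) and immediate early and heat shock genes (0.20; 0.0415) without WT replicate 2. No member of these 8 lists was called over all genes, and adjusted over the list alone Spp1 passed on the chondrogenic list and no other member of the 8. The adipocyte mean of -0.030 and the circadian mean of 0.050 had the opposite sign to their medians. With a pseudocount of 0.01 the medians of the cardiomyocyte, T and NK cell, B cell and plasma cell, neutrophil, mesothelial and proliferation lists were 3.62, 2.19, 2.69, 1.80, 2.15 and 0.73, and with no filter on low values the neutrophil median was 0.67. In total 20 of 30 lists passed the camera test with its preset correlation, none passed camera with an estimated correlation (2 had an unadjusted p under 0.05), and 1, the cardiomyocyte list, passed the directional fry test.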

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

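GC-corrected values were the 1 alternative chosen after the data were examined. The main counts were 100 higher genes, 652 lower genes and 20 lists. The higher count was 33 and the lower count 349 with a filter at a mean of 5 FPKM, where fewer genes were tested and 33 and 348 of these were among the main calls, and 12 lists passed. With sample weights the counts were 285 and 1011. At an adjusted p under 0.1 the higher count was 184, and at an unadjusted p under 0.05 with at least 2-fold it was 211. With an estimated correlation 0 lists passed, and 1 passed the directional fry test. Robust moderation gives no camera value. Leaving out each library gave 37 to 192 higher genes, 389 to 751 lower genes, 15 to 22 lists and log2 fold changes of 1.24 to 2.15 for Spp1 and 0.23 to 0.47 for Fbn1. The adjusted p of Spp1 was 0.0218 to 0.191 over these and 0.0216 with sample weights, where its log2 fold change was 1.52. Fewer samples enter each left-out fit; beyond that the cause of these changes was not tested.

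With the replicate number as a block, 112 genes were higher and 586 lower, 20 lists passed, and Spp1 had a log2 fold change of 1.73 with an adjusted p of 0.0330. Whether the numbers pair the samples was not settled. Deviations from the group means of same-numbered samples correlated at 0.26, -0.024 and 0.097 across genes. The 0.26 of replicate 1 was the highest of all pairs of a WT and a mutant library. Clock genes, given below, also set these libraries apart from the rest. WT replicate 2 correlated best with Fbn1C1041G/+ replicate 3 (0.054), and WT replicate 3 alike with Fbn1C1041G/+ replicates 2 and 3 (0.097 each), so pairing was not shown for these numbers.

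Of 1976 values of 118 named genes under the alternatives, 1816 kept their direction and side of the threshold, 94 lost the call, 45 gained it and 21 changed sign. Of 474 list values, 426 kept both, 18 lost the call, 7 gained it and 23 changed the sign of the median. Gene calls were lost with all libraries in the fit too. With no filter on low values those of Myl3, Igfbp2, Ltbp2, Tcf21, Fcgr1, Lyz2 and Ccl8 ended (limma adjusted p 0.0648 to 0.0757). No gene or list that changed sign was called in the main test, and the cause was not tested. With quantile normalization Acta2 was at -0.032, vasoactive genes at 0.0059, adipocyte genes at -0.026 and circadian genes at 0.041 (0.030 with median-ratio scaling). With sample weights Col1a1 was at -0.20, Eln at -0.011, Tgfb1 at -0.083 and Agt at 0.071, chondrogenic genes at -0.064, vasoactive genes at 0.053 and immediate early genes at -0.066. Without a filter chondrogenic genes were at -0.062, and Acta2 was at -0.0022 with GC correction. Leaving out each library gave log2 fold changes, or list medians, of -0.13 to 0.096 for Acta2, -0.40 to 0.97 for Col1a1, -0.27 to 0.78 for Eln, -0.22 to 0.16 for Mmp2, -0.21 to 1.19 for Tgfb1, -0.039 to 0.29 for Pdgfra, -0.24 to 0.95 for Msln, -0.13 to 0.15 for Atf4, -0.72 to 0.50 for Agt, -0.12 to 0.28 for chondrogenic and osteogenic, -0.022 to 0.12 for vasoactive signalling, -0.020 to 0.20 for endothelial markers, -0.48 to 0.10 for brown adipocyte markers, -0.27 to 0.42 for adipocyte markers, -0.18 to 0.011 for oxidative phosphorylation, -0.14 to 0.20 for immediate early and heat shock and -0.11 to 0.23 for circadian clock.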

Other observations

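The lists in this part that are called added, and all of the tests of explanations and of other splits of the samples here, were chosen after the values were seen. Clock genes set 2 libraries apart from the rest across the groups. Dbp, an output gene of the clock, stood at 89.2 FPKM in WT replicate 1 and 87.5 FPKM in Fbn1C1041G/+ replicate 1, and at 3.31 to 18.7 FPKM in the other 4 libraries. Arntl, which encodes the clock activator BMAL1, ran the other way, at 2.33 and 2.72 FPKM in those 2 libraries and 14.4 to 22.7 FPKM in the other 4. The times of collection are not given in the sources used here. Ucp1, the uncoupling protein of brown fat, stood at 136.9, 300.5 and 1071 FPKM in WT and at 443.9, 372.2 and 96.3 FPKM in Fbn1C1041G/+ replicates 1 to 3.

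Besides Rps27rt, 8 genes were listed at 0 in all 3 libraries of one group and at 1 FPKM or more in all 3 of the other. Of these, Snord99 (3.04, 5.89 and 3.53 FPKM) and Snora33 (2.60, 2.51 and 2.01 FPKM) were listed in WT alone. Cd300ld4, Mir142b, Mir207, Mir615, Mir7026 and Mir7058 were listed in Fbn1C1041G/+ alone, at 1.02 to 5.85 FPKM. In the small RNAs among them, a value of this size rests on few fragments.

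Of the 10 ways to split the 6 samples into 3 and 3, the real one gave 100 higher and 652 lower genes, and the highest count in either direction among the others was 8. For the lists the real split gave 20 past camera with its preset correlation and the others 0, 15, 13, 14, 19, 5, 6, 16 and 14. Camera at this setting thus called many lists in most groupings that mix the genotypes, and the 20 calls are weak evidence. In each case 1 split of 10, the real one, gave as many, and 10 splits are too few for a share under 0.05. A difference between the genotypes adds to the spread within mixed groups, which holds down the gene counts of the other splits.

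Neuronal transcripts were lower in the mutant samples, and an added list of neuronal and sympathetic genes, written after this fall was seen and so a description of it and no test, had 36 of 41 tested members called lower (2 of the 41 are on a fixed list) and a median log2 fold change of -2.11 (quartiles -2.48 and -1.77); Npy, which encodes neuropeptide Y, stood at 1314, 841.5 and 1211 FPKM in WT and 366.7, 183.9 and 107.9 FPKM in Fbn1C1041G/+ replicates 1 to 3. Scaling of a whole library moves all its genes alike. The median log2 fold change over all tested genes was -0.0036, so no shift of all genes near the neuronal median was seen. Median-ratio scaling could therefore move the neuronal median only a little, and its value of -2.07 afterwards was no test of scaling as the cause. The tables argued against a loss of myelinated fibres alone, since the 4 myelin members of the list fixed beforehand had a median of -0.17 (largest SE 0.40). Less ganglion tissue in the mutant samples is a candidate explanation. The 5 glial members of the fixed list were all lower, with a median of -0.85. An added list of 10 glial genes, 5 of them on a fixed list, had a median of -0.84 with 4 called. The glial fall was smaller than the neuronal median of -2.11, and glial genes were asked only to be lower. Myelin genes were asked to fall as far as the neuronal genes, so the 2 explanations were not held to the same rule. Whether a difference in ganglion tissue came from dissection or from the genotype was not tested, and a change of expression within the nerve cells stays open.

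Striated muscle transcripts were higher in the mutant samples, but of different kinds. The added atrial list (median log2 fold change 2.23, 0 of 4 called) and the added list of ventricular and slow muscle (3.64, 1 of 3 called), each with 3 genes that are also on fixed lists, differed in mean log2 value (atrial minus the other) by -2.51, -1.60 and 5.14 in Fbn1C1041G/+ replicates 1 to 3, a range of 7.65, which argues against 1 programme turned on alike in every mutant sample. Myl7, an atrial light chain, stood at 2, 3.43 and 125.7 FPKM and Myl2, one of ventricle and slow skeletal muscle, at 90.6, 33.7 and 0.81 FPKM in these libraries, and since the means of the ventricular and slow list (4.78, 3.95 and 1.11) ran with those of the skeletal list (3.83, 3.61 and 1.603), ventricle and slow skeletal muscle cannot be separated by it. Heart and skeletal muscle tissue taken along in different amounts is a candidate explanation, since the mean of the skeletal muscle list ranged over 2.22 on the log2 scale among the mutant libraries and over 0.37 among WT. That list holds Mb and Ckm, which heart muscle also expresses, so its mean does not by itself show skeletal muscle tissue. An effect of the genotype on how much of such tissue adhered, or on the aorta itself, was not tested.

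Spp1 was higher in all 3 mutant libraries, though not past the threshold, and macrophage markers were higher too. The tables argued against the GC trend of WT replicate 3, since the log2 fold change without that library was 1.77 ± 0.48 (SE; limma adjusted p 0.0971, and 0.0216 to 0.191 over the alternatives), and it was 1.72 with all 6 libraries corrected for GC content, since mutant libraries had such trends too. Relative to the mean of the macrophage list, Spp1 differed between the groups by 0.75 ± 0.30 on the log2 scale (SE, n = 3 each; exact 2-sided permutation p = 0.1, the smallest that 3 against 3 can give). This was 2.53 times its SE and so past the limit of 2 SE that was set first, which would have counted against macrophages as the whole cause, but that limit was replaced after the values were seen by the 95% limit for 4 degrees of freedom, 0.83, which the value did not reach, so more macrophages and more Spp1 per cell cannot be told apart in these 6 samples. An effect of the genotype on Spp1 within a cell type was not tested.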
